A study of Rattus norvegicus with 8 samples.

How the data were processed

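RNA of 4 rat vein grafts and 4 control jugular veins, taken 1 week after the operation, was sequenced as total RNA on Illumina libraries, per the labels' protocols. Reads were aligned with HISAT2 2.0.4 to the rat assembly Rnor_6.0, per the submitters' processing notes. The read counter, the annotation release and whether counting used strand are not given in the sources used here. The deposited values are whole-number counts per gene, as the authors made them, in a table of 37209 named gene rows and 8 columns, each named by a sample title, with no further normalization found in the values. Because strand use is not given, reads of a gene and of an antisense gene over it are not told apart. Reads shared by near-identical copies may have been split or dropped, so values of actins, myosin heavy chains, globins, RT1 genes, Lyz2, Tpsb2, Gapdh and Tpi1 are uncertain. Gene names are those of the table. Of the rows, 20212 carry a current symbol of the GRCr8 RefSeq table, 2810 an older symbol of 1 current gene and 14187 match neither. Members of gene lists were looked up by either kind of symbol, and no coordinates were used.

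Total counts per library were 14267490, 11110154, 12557709 and 5981520 in controls 1 to 4 and 16061189, 12772824, 10533451 and 14581651 in grafts 1 to 4. Every pair of libraries within a group differed by more than sampling noise, so each counts as 1 sample. Groups come from the sample titles. The series' design speaks of 4 pairs and the protocol of the animal's own other jugular vein. The titles number both groups 1 to 4, while the source names number the grafts 9, 10, 3 and 5 and the controls 1, 2, 3 and 4, so which graft belongs to which control is uncertain and the main test is unpaired. No batch or date is given in the labels.

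Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10, which left 15464, holding 99.08% to 99.86% of the counts of each library. Libraries were scaled by TMM factors, which ran from 0.90 to 0.96 in the controls and from 1.03 to 1.19 in the grafts. The group effect was tested with glmQLFit and glmQLFTest, adjusted by Benjamini-Hochberg over all genes tested, and called at an adjusted p under 0.05. "edgeR adjusted p" stands for this value. Fold changes are graft minus control on the log2 scale, with the standard error taken as the absolute fold change over the square root of the test's F. CPM values use the TMM-scaled library sizes and are means ± SD over 4 libraries. Where a group had no counts, the fold is a lower bound against 3 counts over the whole group, and with 1 to 3 counts it is a ratio of summed counts with an exact 95% binomial interval. The edgeR p-values set the group difference against the spread between these libraries, with dispersion estimates shared across genes. Camera's p-values at the preset correlation compare a list's members with the other genes. They do not use how those members vary together between libraries.

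Gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists with at least 5 tested members. The test was repeated with a correlation estimated per list and with fry. The 32 lists cover contractile smooth muscle, matrix and its proteases, endothelium (identity, venous, arterial, flow-responsive), adhesion molecules, chemokines and cytokines, innate receptors, 5 leukocyte types (macrophage, neutrophil, mast, T and NK, B and plasma cells), cell cycle, coagulation, TGF-beta and BMP signalling, osteogenic and chondrogenic genes, 3 parts of energy metabolism, 9 tissues that a vein sample could hold by admixture and the immediate-early response. A list's score in a library is the mean log2 CPM of its tested members with a prior count of 2. Genes named in the text follow a rule. It takes the 6 largest rises and the 6 largest falls among genes past the threshold, with a mean of at least 5 CPM in the higher group, no overlap of the groups and no provisional name. It adds, for each list, the 2 members with the smallest p, 1 in each direction where both passed, and for lists of other tissues also the most abundant member. A gene that this rule takes is not reported here. The main test, the lists and the rule were set before the data were examined.

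The procedure was tested on simulated counts with the mean levels of the control libraries and the library sizes of all samples, in 14716 genes of which 200 were changed. It recovered 1.5% of genes changed 1.5-fold, 38.8% of those changed 2-fold and 84.8% of those changed 4-fold, and 6.7% of its 89 calls were false. In the data a far larger share was called (6538 of 15464 genes). The adjusted threshold depends on that share, so these rates do not carry over to the real test. A raised list of 15 random genes was called and 0 of 20 unchanged lists were. Genes were drawn independently there, whereas estimated correlations within the real lists reached 0.89. The simulation thus does not show how often camera calls lists falsely in these data. Other settings fixed at the same time were RLE and upper-quartile factors, no filter, a stricter filter (1 CPM in at least 4 libraries), the title number as a replicate block, DESeq2 1.42.0, limma voom, glmTreat against a fold change of 1.5, an estimated correlation, fry, and each library left out in turn. Chosen after the data were seen were leaving out controls 3 and 4 together, scaling by library totals alone and thinning each library to the smallest total. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.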

Results

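RNA was sequenced from 8 rat veins taken 1 week after a vein graft operation: 4 vein grafts and 4 control jugular veins of Sprague Dawley rats, an outbred laboratory strain. In this operation the ends of a divided left common carotid artery are turned over short cuffs, so that a vein placed between them carries arterial blood. The control was the jugular vein of the animal's other side, which stayed in the venous circulation. The comparison of the groups shows which transcripts differ between a vein placed in the artery and a vein left in place. Total counts per library ran from 5981520 to 14267490 in the controls and from 10533451 to 16061189 in the grafts, and control 4 had the fewest. At these depths 3 counts correspond to 0.187 to 0.502 CPM (counts scaled to library size), which limits statements on rarer transcripts. Across genes, log2 CPM correlated with Pearson's r of 0.93 to 0.97 between control libraries, 0.96 to 0.98 between graft libraries and 0.79 to 0.86 between the groups. Genes are not independent replicates, so these coefficients only describe the libraries. The first principal component held 67.9% of the variance and parted the 4 grafts from the 4 controls, and the second, with 11.1%, spread the controls.

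Grafts held fewer transcripts of contractile smooth muscle and adipocyte genes than control veins, and more transcripts of macrophage, T cell, cell division, matrix protease, and osteogenic and chondrogenic genes. In these lists 13 of 16 contractile and 16 of 17 adipocyte genes fell, while 18 of 20 macrophage, 17 of 17 T and NK cell, 21 of 28 cell cycle, 13 of 17 protease and 8 of 11 osteogenic and chondrogenic genes rose. The other members did not pass, except Cnn2, which rose, and Timp3, which fell. Camera called each of these lists at its preset correlation and none with an estimated correlation (adjusted p from 0.0953 to 0.307). Synpo2, an actin-binding protein of smooth muscle, went from 1500 ± 354 CPM (SD, n = 4) in the controls to 79 ± 28 CPM (SD, n = 4) in the grafts. Csf1r, the receptor for the macrophage growth factor, went from 79.6 ± 12.6 to 441 ± 78.1 CPM, and Tnc, the matrix protein tenascin-C, from 81.5 ± 17.2 to 2090 ± 961 CPM. Acan, the main proteoglycan of cartilage, went from 0.517 ± 0.33 to 346 ± 246 CPM. Of 15464 genes tested, 6538 changed (42.3%) by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Of these, 3250 rose in the grafts and 3288 fell, a share of 49.7% that rose. Scaling by library totals alone in place of TMM factors gave 4558 that rose and 2164 that fell, or 67.8% that rose. That scaling moved the median log2 fold change of all genes from 0.01 to 0.23, so all changes below are relative to the TMM scale. Among the genes past the threshold, 2024 rose by a log2 fold change of at least 1 and 1605 fell by as much. The graft and control libraries did not overlap for 6281 genes (40.6%), where chance would give 2.86%.

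The genes with the largest rises among those separated between the groups were Msln, Tnn, Plekhg4, Cd5l, Ccl9 and Mmp12. Msln, a surface protein of mesothelial cells, had no counts in the controls and 52.3 ± 13.1 CPM in the grafts, at least 700-fold higher against a floor of 3 counts over the control group. Cd5l, secreted by macrophages, also had no control counts and was at least 138-fold higher against the same floor. Plekhg4, with 1 control count, stood 1440-fold higher (95% counting interval 257 to 56700), and Ccl9, a chemokine of myeloid cells with 3 control counts, 1030-fold higher (95% counting interval 352 to 5000). Tnn, the matrix glycoprotein tenascin-N, rose by a log2 fold change of 10.00 ± 0.82 (SE; edgeR adjusted p = 3.61e-05), and Mmp12, the macrophage elastase, by 9.79 ± 0.88 (edgeR adjusted p = 4.9e-05). The largest falls were those of Thrsp, Otof, Oxtr, Klb, Ankef1 and Mc2r. Among controls, all but Otof were highest in controls 3 and 4, which also had the highest adipocyte scores. Thrsp stood at 68.2 and 89.7 CPM in controls 1 and 2, and at 419 and 1220 CPM in controls 3 and 4. Thrsp, a regulator of lipid synthesis, fell by 10.81 ± 1.30 on the log2 scale (edgeR adjusted p = 0.000214). Otof, Klb (a co-receptor for fibroblast growth factors) and Mc2r (the corticotropin receptor) had no graft counts and were at least 224-fold, 139-fold and 120-fold lower against the 3-count floor. Oxtr, the oxytocin receptor, with 1 graft count, was 1020-fold higher in the controls (95% counting interval 183 to 40400), and Ankef1, with 2, was 909-fold higher (95% counting interval 251 to 7510). Such intervals cover counting error only.

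**Figure D1:**
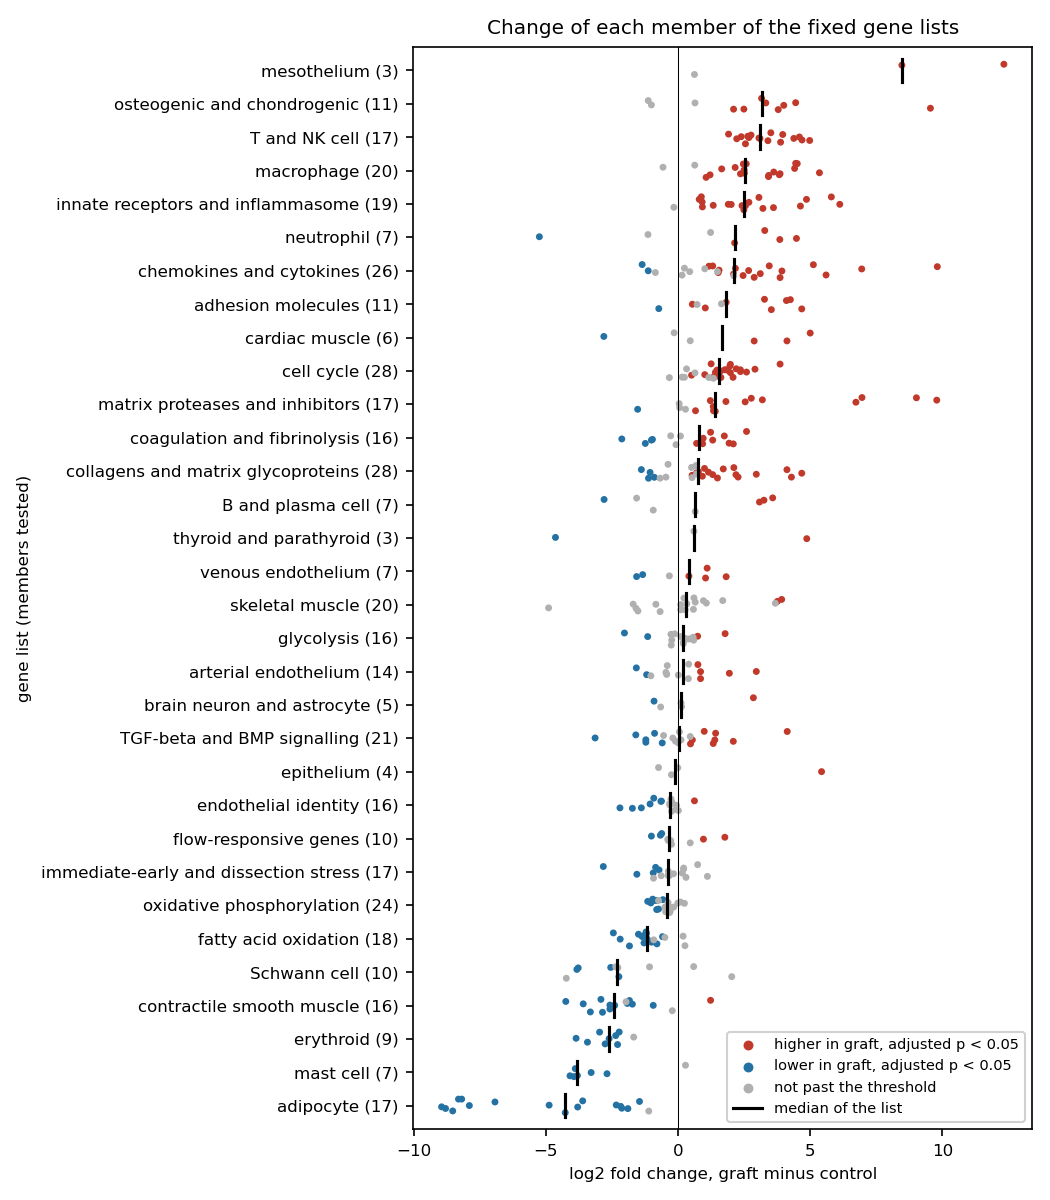
Log2 fold change (graft minus control) of each tested member of the 32 gene lists, 1 row per list with the number of members tested, sorted by the list's median (black bar). Red and blue points are higher and lower in the grafts at an edgeR adjusted p under 0.05 and grey points are not past it. The medians run from -4.27 for adipocyte genes to 8.47 for the 3 mesothelial genes, of which Msln and Wt1 have no control counts (5.60 with both at their bound).

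Genes of 32 lists, fixed before the data were examined, give the account by group. Of the 29 lists with at least 5 tested members, camera with its preset correlation called 9 up and 7 down. With a correlation estimated per list, camera called 0 of the 29 (4 had an unadjusted p under 0.05), while fry, which asks only whether a list moves one way on balance, called 15. Member counts adjusted over the list alone equalled the counts over all genes tested for 26 lists, and the other 6 are given with their list.

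Genes of the contractile apparatus of smooth muscle were lower in the grafts: 13 of 16 fell, 1 rose and 2 did not pass, with a median log2 fold change of -2.43. Synpo2 fell by 4.25 ± 0.31 on the log2 scale (SE; edgeR adjusted p = 2.41e-05). Myh11, the smooth muscle myosin heavy chain, went from 8090 to 672 CPM and Acta2, smooth muscle alpha-actin, from 3320 to 930 CPM, both past the threshold and named here after their values were seen. The exception was Cnn2, a calponin also made by non-muscle cells, which rose by 1.23 ± 0.17 (edgeR adjusted p = 0.000472). The list was called down by camera (adjusted p = 1.65e-10; adjusted p = 0.231 with an estimated correlation). The actins share long stretches of sequence, so reads of Acta2 and Actg2 are uncertain between copies.

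Of 28 collagens and matrix glycoproteins, 16 rose, 4 fell and 8 did not pass (18 and 5 adjusted over the list alone). Tnc rose by a log2 fold change of 4.68 ± 0.36 (SE; edgeR adjusted p = 3.04e-05) and Dcn, the proteoglycan decorin, fell by 1.39 ± 0.23 (edgeR adjusted p = 0.00124). Col3a1 and Col1a1, which led the counts in 7 of the 8 libraries and were singled out after their values were seen, were among those that fell. Their shares of all counts averaged 4.93% ± 0.92 and 4.36% ± 1.62 (SD, n = 4) in the controls and 3.05% ± 0.69 and 2.41% ± 0.75 in the grafts. The log2 fold changes were -0.90 for Col3a1 (edgeR adjusted p = 0.0385) and -1.06 for Col1a1 (edgeR adjusted p = 0.0431). The falls in this list went from 4 to 1 without graft 3, graft 4, control 1, control 2 or control 4, and to 2 without graft 2. Of the fits with 1 library left out, Col1a1 passed only without graft 1 or control 3 and Col3a1 only without control 3, with edgeR adjusted p up to 0.112 for Col1a1 (without graft 4) and 0.107 for Col3a1 (without control 2). Col1a1 also missed the threshold with library totals alone (edgeR adjusted p = 0.0526) or upper-quartile factors (0.0517), and Col3a1 with controls 3 and 4 left out (0.0768). By camera the list was up (adjusted p = 0.000171; adjusted p = 0.581 with an estimated correlation).

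Of 17 matrix proteases and their inhibitors, 13 rose, 1 fell and 3 did not pass. Adamts4, which cuts aggrecan and versican, rose by a log2 fold change of 3.19 ± 0.21 (SE; edgeR adjusted p = 2e-05), and Mmp12 went from 0.294 ± 0.322 to 309 ± 230 CPM. Timp3, an inhibitor of these enzymes bound to the matrix, fell by 1.53 ± 0.22 (edgeR adjusted p = 0.000602). The rises numbered 8 of 19 tested with controls 3 and 4 left out (13 at an unadjusted p under 0.05, with a median of 1.59). Camera called the list up (adjusted p = 3.49e-06; adjusted p = 0.283 with an estimated correlation). Of 11 osteogenic and chondrogenic genes, 8 rose and 3 did not pass, with a median of 3.16. Acan rose by 9.55 ± 0.74 (edgeR adjusted p = 3.11e-05) and Runx2, a transcription factor of bone formation, by 3.16 ± 0.20 (edgeR adjusted p = 2e-05). The collagen of cartilage, Col2a1, did not rise: it stood at 2.54 CPM in the controls and 1.27 CPM in the grafts, not past the threshold and named after its values were seen. Spp1 stands both in this list and in that of macrophages. Without graft 4, 7 of these genes rose and 1 fell, and with DESeq2 8 rose and 1 fell. Camera called these genes up (adjusted p = 0.000171; adjusted p = 0.231 with an estimated correlation).

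**Figure D2:**
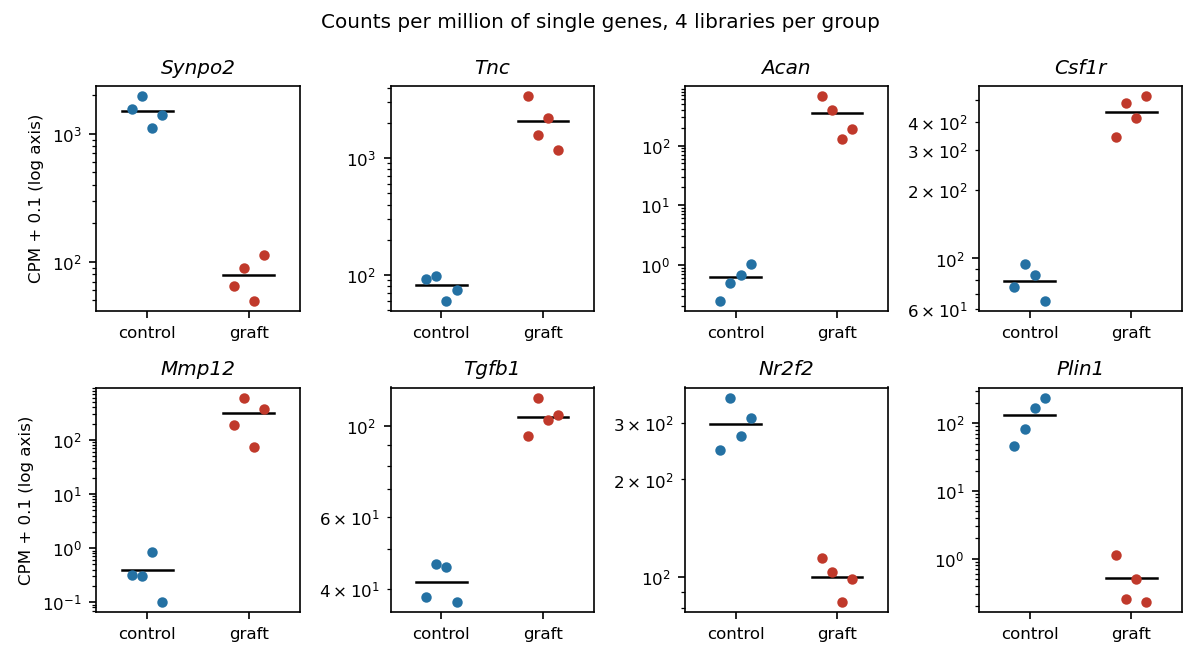
CPM plus 0.1 (log axis) of 8 genes named by the fixed rule in the 4 control (blue) and 4 graft (red) libraries, with the group mean as a bar. Each panel has its own axis, and in each the 4 graft libraries lie on one side of the 4 controls, as Acan with 0.15 to 0.933 CPM in the controls and 127 to 671 CPM in the grafts.

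Macrophage genes rose: 18 of 20, with 2 not past the threshold and a median log2 fold change of 2.54. Trem2, a lipid-sensing receptor of macrophages, rose by 3.86 ± 0.25 (SE; edgeR adjusted p = 2e-05) and Csf1r by 2.47 ± 0.18 (edgeR adjusted p = 2.31e-05). The members that did not pass were Cd163, at -0.57, and Msr1, at 0.63, both scavenger receptors and named after their values were seen. With no low-count filter 22 were tested, of which 19 rose and 1 fell. Of 19 innate receptors and inflammasome genes, 18 rose and 1, Nod2, stood at -0.16 and did not pass. Tlr9 and Tlr2, receptors for microbial DNA and lipoproteins, rose by 4.63 ± 0.32 (edgeR adjusted p = 2.15e-05) and 3.06 ± 0.24 (edgeR adjusted p = 3.18e-05). Camera called both lists up (adjusted p = 4.79e-20 and 5.23e-14; adjusted p = 0.0953 for each with an estimated correlation). Of 26 chemokines and cytokines, 17 rose, 2 fell and 7 did not pass. Cxcl12, a ligand of Cxcr4, rose by 1.55 ± 0.12 (edgeR adjusted p = 3.41e-05) and Il33, an alarm cytokine of stromal and endothelial cells, fell by 1.13 ± 0.22 (edgeR adjusted p = 0.00271). The falls numbered 1 without graft 1, control 2, control 3 or control 4, with controls 3 and 4 left out, or with library totals alone. Of 11 adhesion molecules, 8 rose, 1 fell and 2 did not pass. Selplg, the leukocyte ligand of P-selectin, rose by 4.10 ± 0.27 (edgeR adjusted p = 2e-05) and Icam2 fell by 0.73 ± 0.16 (edgeR adjusted p = 0.00521). Camera called chemokines (adjusted p = 4.39e-07; adjusted p = 0.225 with an estimated correlation) and adhesion molecules (adjusted p = 5.23e-07; adjusted p = 0.0953 with an estimated correlation) up.

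All 17 tested T and NK cell genes rose, with a median of 3.10 and a range from 1.91 to 4.98. Cd4 rose by 2.55 ± 0.19 (SE; edgeR adjusted p = 2.62e-05) and Cd2 by 3.96 ± 0.39 (edgeR adjusted p = 7.02e-05). The levels differed: Cd4, which rat macrophages also carry, reached 264 ± 52.2 CPM in the grafts and Cd2, a T and NK cell receptor, 8.96 ± 2.82 CPM. As a list they were up by camera (adjusted p = 1.82e-09; adjusted p = 0.231 with an estimated correlation). Of 7 neutrophil genes, 4 rose and 1 fell (2 adjusted over the list alone, and 2 without control 1 or with DESeq2). With limma voom 2 rose and 1 fell, and of 4 tested in thinned counts 2 rose and 0 fell (0 also at an unadjusted p under 0.05, by edgeR). With controls 3 and 4 left out 1 rose and 1 fell (4 and 2 at an unadjusted p under 0.05, by edgeR). With all libraries camera did not call the list (adjusted p = 0.402). Csf3r rose by 3.85 ± 0.63 (edgeR adjusted p = 0.00112), from 7.64 CPM in graft 4 to 56.7 CPM in graft 2, and Mpo, made in neutrophil precursors, fell by 5.25 ± 1.00 (edgeR adjusted p = 0.00258). Of 7 B and plasma cell genes, 3 rose and 1 fell (4 and 4 of 10 tested with controls 3 and 4 left out), and camera did not call the list (adjusted p = 0.289). Blnk, an adaptor of the B cell receptor that macrophages also make, rose by 3.58 ± 0.42 (edgeR adjusted p = 0.000174) and the complement receptor Cr2 fell by 2.80 ± 0.72 (edgeR adjusted p = 0.0119). The groups overlapped for Cr2, which stood at 10.2, 18.1, 4.02 and 1.49 CPM in controls 1 to 4 and at 0.578 to 2.25 CPM in the grafts. Of 7 mast cell genes, 6 fell and 1, Kit, stood at 0.28. Hdc, which makes histamine, fell by 2.69 ± 0.38 (edgeR adjusted p = 0.000492) and Ms4a2, the beta chain of the IgE receptor, by 3.94 ± 0.73 (edgeR adjusted p = 0.00228). Camera called the mast cell list down (adjusted p = 0.00654; adjusted p = 0.559 with an estimated correlation). With controls 3 and 4 left out, 3 mast cell genes fell, and these controls had the highest mast cell scores (4.32 and 4.05 as mean log2 CPM, against 2.24 and 3.60 in controls 1 and 2). In that smaller fit the median was -3.02, and 6 fell and 1 rose at an unadjusted p under 0.05. The grafts' mean lay below controls 1 to 4 by medians of -2.26, -3.72, -4.40 and -4.16, so the fall does not rest on controls 3 and 4 alone.

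Of 28 cell cycle genes, 21 rose and 7 did not pass (23 rose adjusted over the list alone), with a median of 1.54. Mcm2 and Mcm3, subunits of the replicative helicase, rose by 1.47 ± 0.13 (SE; edgeR adjusted p = 4.42e-05) and 1.61 ± 0.17 (edgeR adjusted p = 0.000106). Levels stayed moderate, with Mcm2 at 37 ± 3.61 CPM in the grafts against 13.4 ± 0.767 CPM in the controls. Camera called the list up (adjusted p = 2.83e-09; adjusted p = 0.264 with an estimated correlation).

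Endothelial genes moved less than those of smooth muscle. Of 16 tested, 7 fell, 1 rose and 8 did not pass, with a median of -0.32. Emcn, the sialomucin endomucin of venous and capillary endothelium, fell by 1.73 ± 0.21 (SE; edgeR adjusted p = 0.000229), and Vwf, von Willebrand factor, named after its values were seen, fell from 2210 to 479 CPM. Eng, a co-receptor for TGF-beta, rose by 0.62 ± 0.18 (edgeR adjusted p = 0.0196). Eng was not past the threshold without graft 1 (edgeR adjusted p = 0.0519), without control 4 (0.054) or with controls 3 and 4 left out (0.126). Camera called endothelial genes down (adjusted p = 0.0153; adjusted p = 0.283 with an estimated correlation). Of 7 genes of venous endothelium, 4 rose and 2 fell. Nr2f2, the transcription factor that sets venous identity, fell by 1.57 ± 0.15 (edgeR adjusted p = 6.79e-05), while Aplnr, the apelin receptor, rose by 1.10 ± 0.12 (edgeR adjusted p = 0.000156). Of 14 genes of arterial endothelium, 5 rose and 2 fell. Unc5b, a netrin receptor, rose by 1.94 ± 0.19 (edgeR adjusted p = 6.99e-05) and Gja5, the gap junction protein connexin 40, fell by 1.19 ± 0.34 (edgeR adjusted p = 0.0181). Gja5 was not past the threshold without graft 2 (edgeR adjusted p = 0.0523) or with library totals alone (0.0566). The arterial falls numbered 4 without control 1, 0 with library totals alone (2 at an unadjusted p under 0.05), and 1 with controls 3 and 4 left out or without graft 1, graft 3, graft 4, control 2, control 3 or control 4. Of 10 flow-responsive genes, 2 rose and 3 fell. Piezo1, a mechanically gated channel, rose by 0.96 ± 0.14 (edgeR adjusted p = 0.000639) and Thbd, thrombomodulin, fell by 1.01 ± 0.15 (edgeR adjusted p = 0.000602). Camera called none of these 3 lists (venous adjusted p = 0.811, arterial 0.332, flow-responsive 0.686). Fry called the arterial list up (fry adjusted p = 0.00597), but not the venous (0.211) or flow-responsive list (0.362).

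Of 16 coagulation and fibrinolysis genes, 9 rose, 4 fell and 3 did not pass. Plat, the tissue plasminogen activator, rose by 1.31 ± 0.15 (SE; edgeR adjusted p = 0.000184), and Procr, the endothelial protein C receptor, fell by 0.97 ± 0.13 (edgeR adjusted p = 0.000469). Thbd, the partner of Procr in protein C activation, fell as given above. Of 21 genes of TGF-beta and BMP signalling, 8 rose, 6 fell and 7 did not pass. The ligands went apart: Tgfb1 rose by 1.33 ± 0.12 (edgeR adjusted p = 5.01e-05) and Bmp4 fell by 3.14 ± 0.26 (edgeR adjusted p = 3.73e-05), from 96.7 ± 19.8 to 10.9 ± 3.84 CPM. Camera called neither list (coagulation adjusted p = 0.325, TGF-beta and BMP 0.811). Fry called the coagulation list up (fry adjusted p = 0.0288), but not that of TGF-beta and BMP (0.434).

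Genes of fatty acid oxidation were lower in the grafts: 14 of 18 fell and 4 did not pass, with a median of -1.18. Acaa2, a thiolase of mitochondrial beta-oxidation, fell by 2.19 ± 0.29 (SE; edgeR adjusted p = 0.000337), and Ech1, an enzyme of the same pathway, by 1.02 ± 0.20 (edgeR adjusted p = 0.00271). Controls 3 and 4 carried the highest adipocyte scores (7.36 and 7.99, against 5.55 and 5.71 in controls 1 and 2). With both left out, 6 of the 18 fell, the median was -0.39 and camera no longer called the list (adjusted p = 0.0621). The falls numbered 9 with limma voom, 9 without graft 2 or control 3, and 8 without graft 3 or control 4. Of 24 genes of oxidative phosphorylation, 8 fell and 16 did not pass. Sdhc, a subunit of succinate dehydrogenase, fell by 0.96 ± 0.20 (edgeR adjusted p = 0.00445) and Cox6c, a subunit of cytochrome c oxidase, by 0.93 ± 0.24 (edgeR adjusted p = 0.0107). With controls 3 and 4 left out 1 of them fell, and the count was 4 with library totals alone or without graft 1, graft 2 or control 3, 3 without control 4 and 2 without graft 3. Cox6c was not past the threshold with controls 3 and 4 left out (edgeR adjusted p = 0.107), where Sdhc stood at -0.60. Camera called both lists down, fatty acid oxidation with adjusted p = 0.00202 (adjusted p = 0.613 with an estimated correlation) and oxidative phosphorylation with adjusted p = 0.0236 (adjusted p = 0.775 with an estimated correlation). Fry called neither list (fry adjusted p = 0.052 and 0.127). Camera's call of oxidative phosphorylation ended without graft 3 (adjusted p = 0.0567), without control 4 (adjusted p = 0.133) and with controls 3 and 4 left out (adjusted p = 0.327, with a median of -0.19). Of 16 glycolysis genes, 2 rose and 2 fell. Pfkp, a phosphofructokinase, fell by 2.03 ± 0.27 (edgeR adjusted p = 0.000413) and Slc16a3, a lactate exporter, rose by 1.78 ± 0.43 (edgeR adjusted p = 0.00911), though not past the threshold with controls 3 and 4 left out (0.0768, as edgeR adjusted p). The median of the glycolysis list was 0.20 while camera's direction was down (adjusted p = 0.963), so the signs differ. The rises in glycolysis numbered 1 without graft 3, control 2 or control 3 and 4 with library totals alone, and with controls 3 and 4 left out 3 rose and 1 fell. Processed copies of glycolysis genes in the genome make their counts uncertain, and Gapdh had only 45.7 CPM in the controls.

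Markers of tissues around the vein differed between libraries and between groups. Of 17 adipocyte genes, 16 fell and 1 did not pass (17 fell adjusted over the list alone), with a median of -4.27. Plin1 and Retn, which encode the lipid droplet coat protein perilipin and the hormone resistin, fell by 8.19 ± 0.74 (SE; edgeR adjusted p = 4.99e-05) and 7.90 ± 0.66 (edgeR adjusted p = 3.83e-05). Scd1, a fatty acid desaturase and the most abundant member, ran from 77.2 to 6140 CPM in the controls and from 7.14 to 21.2 CPM in the grafts. Camera called the list down (adjusted p = 6.42e-10; adjusted p = 0.307 with an estimated correlation), and 14 members fell with controls 3 and 4 left out. Of 10 Schwann cell genes, 4 fell and 6 did not pass, and camera did not call the list (adjusted p = 0.158), although it did without graft 3 (0.0317), control 1 (0.0415) or control 2 (0.028), with no low-count filter (0.0198) and with library totals alone (0.0423). Without graft 2, 1 of 11 rose and 3 fell. Pmp22 and Mbp, proteins of peripheral myelin, fell by 2.55 ± 0.65 (edgeR adjusted p = 0.0114) and 3.83 ± 1.03 (edgeR adjusted p = 0.0142). Mbp stood at 647 and 592 CPM in controls 3 and 4, and at 37.1 and 48.6 CPM in controls 1 and 2. With controls 3 and 4 left out, the log2 fold changes of Pmp22 and Mbp were -0.57 and -0.89, 0 of the 10 were past edgeR's adjusted threshold and 1 was lower at an unadjusted p under 0.05.

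Skeletal muscle genes stood high in control 3 and in grafts 1, 3 and 4 (scores 5.91, 5.23, 4.03 and 5.44) and low in controls 1 and 2 and graft 2 (0.52, 0.59 and 0.31), with control 4 at 3.39. Of 20 tested, 2 rose and 18 did not pass (1 adjusted over the list alone), and camera did not call the list (adjusted p = 0.505). Tnnt1, the slow troponin T, rose by 3.92 ± 0.88 (SE; edgeR adjusted p = 0.00613) and Myh1, a fast myosin heavy chain, by 3.76 ± 1.20 (edgeR adjusted p = 0.0307). Myh1 missed the threshold without graft 1 (0.0515), graft 4 (0.077), control 1 (0.0547), control 2 (0.0707) or control 4 (0.0724), as edgeR adjusted p, and with limma voom (limma adjusted p = 0.119). Neb, the giant filament protein nebulin and the most abundant member, ran from 26.8 to 366 CPM in the controls and from 25.5 to 426 CPM in the grafts. The rises numbered 1 without graft 1 or graft 4, 4 without graft 2 and 5 without control 3, and 9 with controls 3 and 4 left out. They numbered 4 with no low-count filter, 3 (with 1 fall) with DESeq2 and 1 with limma voom, and 1 gene fell without control 1 or control 2. Camera called the list up without control 3 (adjusted p = 0.0236) or graft 2 (adjusted p = 0.0314) and with controls 3 and 4 left out (adjusted p = 0.00145). Of 6 cardiac muscle genes, 3 rose and 1 fell (1 and 1 with limma voom), and camera did not call them (adjusted p = 0.531). Tnnt2, a troponin T of heart and of developing skeletal muscle, rose by 4.12 ± 0.74 (edgeR adjusted p = 0.00191) to 5.08 CPM. Ryr2, the calcium release channel of heart and smooth muscle, fell by 2.81 ± 0.58 (edgeR adjusted p = 0.00411). Reads of the myosin heavy chains can be split between near-identical copies.

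**Figure D3:**
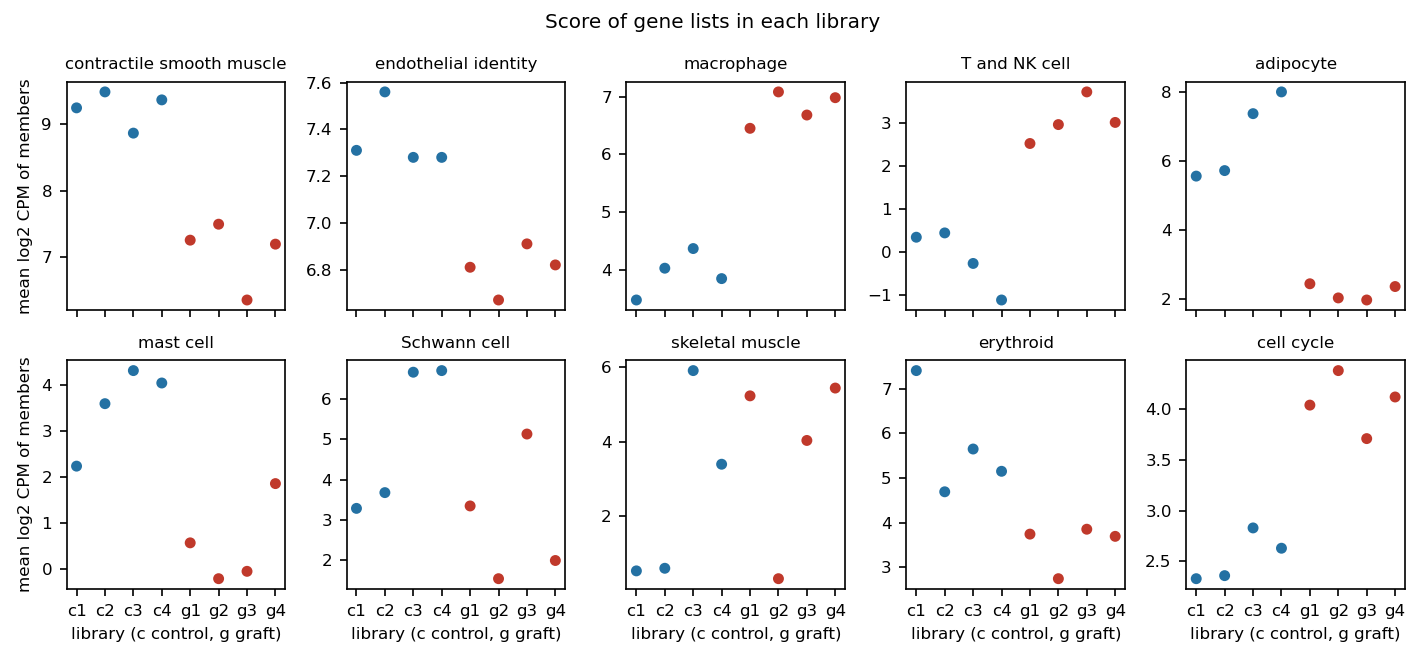
Mean log2 CPM of the tested members of 10 gene lists in each library (c1 to c4 control, g1 to g4 graft), each panel with its own axis. Adipocyte scores run from 5.55 to 7.99 in the controls and from 1.96 to 2.43 in the grafts, while skeletal muscle scores are high in control 3 and in grafts 1, 3 and 4 and low in graft 2 (0.31).

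Of 9 erythroid genes, 8 fell and 1 did not pass. Epb42, a protein of the red cell membrane skeleton, fell by 2.36 ± 0.47 (SE; edgeR adjusted p = 0.00321). Hba1, an alpha-globin and the most abundant member, stood at 6140 CPM in control 1, at 868 to 1130 CPM in the other controls and at 215 to 766 CPM in the grafts. Its fall of 2.29 ± 0.68 (edgeR adjusted p = 0.0226) was not past the threshold without graft 1 (0.0519), graft 2 (0.0559) or graft 4 (0.059), its log2 fold change was -1.12 without control 1, still past the threshold, and globin copies share reads. Camera called the list down (adjusted p = 0.00425; adjusted p = 0.581 with an estimated correlation). Fry did not call the erythroid list (fry adjusted p = 0.0505). Of 17 immediate-early and stress genes, 5 fell and 12 did not pass (3 adjusted over the list alone). Fosb and Btg2 fell by 2.83 ± 0.63 (edgeR adjusted p = 0.00573) and 0.94 ± 0.21 (edgeR adjusted p = 0.00565). Fosb stood at 57.4 CPM in control 1 and at 8.27 to 16.6 CPM in the other controls, and its log2 fold change without control 1 was -1.86, still past the threshold. Control 1 had the highest score of this list (5.62, against 4.42 to 4.61 in the other controls), and without it 5 rose and 3 fell. The falls numbered 3 without graft 1 or graft 2 or with upper-quartile factors, and 2 with library totals alone. With DESeq2 1 rose and 5 fell, with limma voom 1 rose and 4 fell, and camera did not call the list (adjusted p = 0.377).

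The extract protocol in the labels names prefrontal cortex, although the tissue given for each sample is a vein. Of 18 genes of brain neurons and astrocytes, 5 had enough counts to be tested, 1 rose and 1 fell, and camera did not call the list (adjusted p = 0.938). Stmn2, a neuronal microtubule protein, rose by 2.85 ± 0.48 (SE; edgeR adjusted p = 0.00136) to 23.4 ± 15.7 CPM. Slc1a3, a glutamate transporter and the most abundant member, went from 77.9 to 41.3 CPM (edgeR adjusted p = 0.0425). It missed the threshold without any of 6 libraries (graft 1 to 4, control 3 or control 4), with edgeR adjusted p from 0.0675 to 0.121. It also missed it with upper-quartile factors (edgeR adjusted p = 0.0537), library totals alone (0.116), thinned counts (0.062), limma voom (limma adjusted p = 0.0912) and controls 3 and 4 left out (edgeR adjusted p = 0.575, with a log2 fold change of -0.16). Of 3 tested thyroid and parathyroid genes, Pax8 rose by 4.87 ± 0.76 (edgeR adjusted p = 0.000899) and Tshr, the thyrotropin receptor that adipocytes also carry, fell by 4.64 ± 0.71 (edgeR adjusted p = 0.000785). Of 4 tested epithelial genes 1 rose, Cldn4, with 2 control counts and a ratio of 50.3 (95% counting interval 13.7 to 419), and the list's median of -0.13 and mean of 1.11 differ in sign. Cdh1, or E-cadherin, the most abundant of them, stood at 12.4 ± 11.8 CPM in the controls and 10.3 ± 5.68 CPM in the grafts and did not pass (edgeR adjusted p = 0.818), with a log2 fold change of -0.25 that turned to 0.01 with library totals alone, 0.65 with limma voom, 0.17 without control 3 and 0.27 without control 4. Cdh1 passed as higher in the grafts with controls 3 and 4 left out, at 2.19 (edgeR adjusted p = 0.0256), where 3 of 7 tested epithelial genes rose. Of 3 tested mesothelial genes 2 rose: Msln, given above, and Wt1, a transcription factor of mesothelium, which had no control counts, 3.60 ± 0.435 CPM in the grafts and was at least 48.5-fold higher against the 3-count floor. The epithelial, thyroid and mesothelial lists were too short for camera.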

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

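Each of 219 sets of 4 libraries was checked for a highest or lowest library whose gap to its nearest neighbour divided by the whole range, exceeded Dixon's 95% critical value, and 15 did. Chance alone gives about 1 in 20. The check covers library measures, list scores and named genes, and it left out genes with at most 3 counts over a group. Amy1a was added to it after its values were seen.

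Mitochondrial genes took 2.32% of counts in graft 4 and 3.81% to 4.04% in the other grafts (gap over range 0.87). Among list scores, given as mean log2 CPM, control 2 stood highest for endothelial identity at 7.56, against 7.28 to 7.31 in the other controls (0.91). Control 1 stood lowest for arterial endothelium at 4.48, against 4.78 to 4.84 (0.84), and lowest for the 3 tested thyroid and parathyroid genes at -0.07, against 1.22 to 1.28 (0.95). Control 1 also stood highest for immediate-early and stress genes at 5.62, against 4.42 to 4.61 (0.84). Graft 1 stood lowest for innate receptors at 4.83, against 5.25 to 5.31 in the other grafts (0.88). Graft 3 stood lowest for TGF-beta and BMP signalling at 5.65, against 6.09 to 6.17 (0.86), and graft 2 lowest for erythroid genes at 2.74, against 3.69 to 3.85 (0.85).

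Among single genes, given as log2 CPM, Hba1 stood at 12.6 in control 1, with 10.1 in the nearest control (0.87). Tlr9 was highest in control 1 at 0.92, against 0.22 in the nearest (0.83), and Dcn highest in control 2 at 12.1, against 11.7 (0.86). Ech1 was highest in control 3 at 6.45, against 5.69 in the nearest control (0.89). Mbp was highest among grafts in graft 3 at 5.81, against 3.78 in the nearest (0.86), and Scd1 lowest in graft 2 at 2.87, against 4.30 in the nearest (0.92). Amy1a, an amylase of saliva and pancreas, stood at 12.6 in control 3, where it took 0.606% of all counts, with 1.35 in the nearest control (0.86). With all libraries Amy1a was called lower in the grafts, at a log2 fold change of -11.13 (edgeR adjusted p = 0.0203), and without control 3 the value was -0.93 (edgeR adjusted p = 0.272), so the size rests on that library. With all libraries kept, limma voom gave -4.42 (limma adjusted p = 0.47). It also missed the threshold with controls 3 and 4 left out, at -1.22 (edgeR adjusted p = 0.188), and without graft 1, graft 3 or graft 4 (edgeR adjusted p = 0.0553, 0.0546 and 0.0553).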

How the results depend on the processing

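The settings with library totals alone, with thinned counts and with controls 3 and 4 left out together were chosen after the data were seen, and the others were planned. Across scalings, filters and tests at any fold change, 5894 to 7087 genes changed, and every gene called in both an alternative and the main test kept its direction. With controls 3 and 4 left out 4778 genes changed, and with single libraries left out 5588 to 7840 (without graft 2 and without control 1), of which 2845 to 4054 rose and 2742 to 3786 fell. Tested against a fold change of 1.5, 3172 genes changed, 1744 higher and 1428 lower, since that test asks for a larger change. With library totals alone 2164 genes fell and 4558 rose, in place of 3288 and 3250. The TMM factors part the groups, at 0.90 to 0.96 in the controls and 1.03 to 1.19 in the grafts. Leaving them out therefore raises the grafts against the controls for all genes. Why the factors differ was not tested. DESeq2 gave no adjusted p for 29 genes.

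Camera called 15 to 17 of 29 lists with single libraries left out, as against 16. With an estimated correlation it called 0 (4 at an unadjusted p under 0.05). That setting widens the error of lists whose members vary together, and it also tests with the few residual degrees of freedom of 8 libraries. Lists with a low estimated correlation lost their call too, such as adhesion molecules (correlation 0.12, camera adjusted p = 0.0953) and endothelial identity (0.07, camera adjusted p = 0.283). Fry called 15. Against camera's calls it added arterial endothelium and coagulation, and dropped fatty acid oxidation, oxidative phosphorylation and erythroid genes.

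No pairing by title number was seen: deviations from the group mean correlated at -0.07, 0.18, 0.07 and 0.05 for numbers 1 to 4. Only 2 of 8 libraries correlated best with their own number, control 2 and graft 2 with each other. The libraries of a group also differ in adipocyte and skeletal muscle scores, which can hide a likeness by animal, so these correlations do not exclude such a pairing. With the number as a replicate block 5902 genes changed, 3042 higher and 2860 lower. In that fit Amy1a stood at -4.23 (edgeR adjusted p = 0.261) and Slc1a3 at -0.79 (edgeR adjusted p = 0.0753), neither past the threshold, camera called the Schwann cell list down (adjusted p = 0.0419), and 9 fatty acid oxidation genes fell in place of 14. Of osteogenic and chondrogenic genes 7 rose and 1 fell, and 2 neutrophil genes fell in place of 1. A pairing by animal that the titles do not give stays untested.

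The direction turned for Cdh1, for 6 lists that camera had not called and for the epithelial and thyroid lists, which were too short for camera. For Cdh1 (-0.25) the log2 fold change was 0.37 with the replicate block, 0.65 with limma voom, 0.01 with library totals alone, 2.19 with controls 3 and 4 left out, which hold its highest control values (there past the threshold, edgeR adjusted p = 0.0256), and -0.69 to 0.27 with single libraries left out. The median for brain genes (0.11) was -0.12 with no filter, -0.28 with the replicate block, -0.33 with limma voom and -0.27 with thinned counts (3 tested). That for epithelial genes (-0.13) was 0.30 with the replicate block, 0.43 with limma voom, 0.11 with library totals alone and 1.24 with controls 3 and 4 left out (7 tested), that for thyroid and parathyroid genes (0.60) was -0.22 with thinned counts (2 tested), and that for B and plasma cells (0.65) was -0.76 with controls 3 and 4 left out. With single libraries left out the medians ran from -0.69 to 0.26 for brain, -0.27 to 0.35 for epithelium, -0.76 to 2.20 for B and plasma cells, -0.09 to 2.87 for skeletal muscle, -0.09 to 0.17 for TGF-beta and BMP, 0 to 0.28 for arterial endothelium and -0.44 to 0.01 for immediate-early genes. The cause was not tested. Depth limits rare transcripts: thinned to the smallest library, 13975 genes could be tested and 5894 changed.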

Other observations

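All 10 lists in this and the next paragraph were chosen after the data were seen, so their tests describe these libraries only. The 6 tested MHC class II genes rose, with a median log2 fold change of 3.57 (camera adjusted p = 5.45e-06; adjusted p = 0.121 with an estimated correlation). They include Cd74, the invariant chain, which went from 119 ± 45.8 to 997 ± 369 CPM (SD, n = 4), and Ciita, the transcription factor that drives these genes. All 6 genes of the phagocyte oxidase rose, with a median of 3.15 (camera adjusted p = 1.68e-09; adjusted p = 0.0698 with an estimated correlation), among them Cybb, its catalytic subunit, by 4.07 ± 0.33 (SE; edgeR adjusted p = 3.55e-05). Of 9 dendritic and antigen-presenting cell genes 7 rose (camera adjusted p = 6.92e-05; adjusted p = 0.121 with an estimated correlation), including Flt3 and Clec9a. Of 17 complement genes 11 rose and 3 fell (camera adjusted p = 0.00031; adjusted p = 0.198 with an estimated correlation). C3 rose by 4.27 ± 0.64 (edgeR adjusted p = 7e-04), while C7, a part of the membrane attack complex, and Cd59, which blocks that complex, fell by 1.42 ± 0.32 (edgeR adjusted p = 0.00641) and 1.56 ± 0.24 (edgeR adjusted p = 0.000836). Of 20 interferon-stimulated genes 8 rose and 12 did not pass (camera adjusted p = 0.00918; adjusted p = 0.502 with an estimated correlation), with Ifit1 at -1.40 and Mx2 at -0.01 among the latter.

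Of 13 genes of lipid uptake and efflux 9 rose and 1 fell (camera adjusted p = 1.03e-05; adjusted p = 0.121 with an estimated correlation). Olr1, a receptor for oxidized lipoprotein, rose by 6.19 on the log2 scale and Apoe by 2.10, while Cd36, a fatty acid transporter that adipocytes also carry, fell by 1.53. Of 13 smooth muscle ion channel genes 9 fell and 1 rose (camera adjusted p = 6.92e-05; adjusted p = 0.0698 with an estimated correlation). Kcnma1, the large-conductance calcium-activated potassium channel, went from 87.7 to 10.4 CPM, and Trpc6 was the member that rose, from 9.74 to 25.4 CPM. Of 9 eicosanoid genes 3 rose and 2 fell, and camera did not call them (adjusted p = 0.279). Tbxas1, thromboxane synthase, rose by 3.53, and Ptgs2, the inducible cyclooxygenase, fell by 2.97. Of 15 basement membrane laminins and integrins 5 fell (camera adjusted p = 0.11), among them Itga1, Lama2 and Lamb2. All 5 tested developmental skeletal muscle genes rose (camera adjusted p = 0.0143; adjusted p = 0.327 with an estimated correlation), mainly in grafts 1, 3 and 4, which also stood high for adult skeletal muscle. The list named 10 genes, and its members Tnnt2, Actc1 and Myl4 are also the cardiac muscle genes that rose. The groups overlapped for Myh3, Actc1 and Myl4, graft 2 stood at 2.03 CPM of Myh3 and 1.28 CPM of Myh8 against up to 2.05 and 1.27 CPM in the controls, and Myh3 missed the threshold with limma voom (limma adjusted p = 0.161). Of 291 long noncoding RNAs tested, 50 rose and 52 fell, and Miat rose by 3.52.

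The tests of the 3 patterns in the following paragraphs were chosen after the results were seen. Those of fatty acid oxidation and of developmental muscle genes replaced an earlier form that had split the controls by score or used genes picked for the pattern, and the first still leaves out controls picked by score. The count of splits was planned. Of the 35 ways to split the 8 libraries into 4 and 4, only the real 1 gave as many changed genes (6538). The highest other split gave 1, and no rarer result is possible with 35 splits. Each other split mixes grafts with controls, which widens the spread within the sets it compares and keeps its count low. Chance is therefore not excluded by this count. For the number of lists called by camera, 11 of the 35 splits gave at least the real 16 (the highest other gave 20). The others among these 11 set 3 libraries of 1 group with 1 library of the other, and so keep part of the group difference. The splits therefore do not decide whether chance gives that number.

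Contractile smooth muscle genes fell in the grafts. If the endothelium stayed otherwise unchanged, which was not tested, cells entering the wall would dilute smooth muscle and endothelial genes alike. The smooth muscle score minus the endothelial score differed by -1.61 on the log2 scale, with every graft below every control (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 can give). This and the permutation p-values below take the 8 libraries as unpaired, although the series' design speaks of 4 pairs, and would be larger if only swaps within pairs were allowed. Loss of smooth muscle cells that kept their expression would leave the ratios between their genes in place, but for 7 of 21 gene pairs the ratio parted all grafts from all controls, with Synpo2 in 5 of the 7. By the scores, smooth muscle genes fell more than endothelial genes, which equal dilution of both alone would not give. Endothelial genes did not move alike, from -2.20 to 0.62 on the log2 scale, so an otherwise unchanged endothelium is in doubt. The list scores had also been seen before this test was chosen. What part dilution had is therefore not decided. The ratios rest mainly on Synpo2, so they do not exclude loss of cells as the cause. Lower expression of contractile genes within cells that stayed was not tested directly and stays open, as does loss of some smooth muscle cells or of a kind rich in Synpo2.

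Adipocyte and fatty acid oxidation genes fell in the grafts. Equal dilution of adipocyte and endothelial genes by entering cells would not alone give the difference of their scores. Endothelial genes did not move alike, as given above, so what part dilution had is not decided here either. The adipocyte score minus the endothelial score differed by -3.9 on the log2 scale (exact permutation p = 0.0286, two-sided), with every graft below every control. The median fall with controls 3 and 4 left out was 0.33 of that with all controls for fatty acid oxidation genes and 0.69 for adipocyte genes, but these controls were picked for high scores, which made a smaller fall certain, so whether fat attached to control veins is the source stays open. The grafts' mean lay below controls 1 to 4 by medians of -0.30, -0.53, -1.46 and -1.98 for fatty acid oxidation and -3.13, -2.63, -4.40 and -5.49 for adipocyte genes, of which Fabp4, Pparg and Lpl are also made by endothelial cells or macrophages. Whether fat was trimmed from the grafts or was lost from around them in the animal was not tested.

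Skeletal muscle genes stood high in some libraries of both groups, and 13 of 20 were highest in the same 4, control 3 and grafts 1, 3 and 4; these have the list's highest scores, so the count restates them, and pieces of muscle attached to those veins stay an open explanation. Against the adult muscle list the grafts held more of 6 developmental genes (Myh3, Myog, Chrng, Chrna1, Tmem8c and Myod1), which gave 10.5%, 3.41%, 5.81% and 4.72% of the adult muscle list's counts in grafts 1 to 4, and 0.917%, 1.22%, 0.123% and 0.467% in controls 1 to 4. The means differed 8.98-fold (exact permutation p = 0.0286, two-sided), although graft 2 rests on 34 developmental counts and controls 1, 2 and 4 on 12, 11 and 11, and Myh3 alone gave 2384 of 2608, 457 of 516 and 1120 of 1284 of them in grafts 1, 3 and 4 (the other 5 genes gave 0.602% to 0.906% in the grafts and 0% to 0.333% in the controls). Reads shared between myosin copies stay open for Myh3, since Myh8 had 805, 326 and 1282 counts in grafts 1, 3 and 4 and 14 in control 3. A difference between the muscles next to the carotid and the jugular site stays open too, since the design places grafts and controls apart, and no cause within the muscle was tested. Myh4, another myosin of the adult list, gave 9786 of 31595 adult counts in control 3 and 489 of 2355 in control 4. It gave 189 of 24723, 42 of 8879 and 235 of 27231 in grafts 1, 3 and 4. In controls 1 and 2 and graft 2, with few muscle counts, it gave 5 of 1309, 13 of 901 and 4 of 996. The adult counts thus differed in make-up between libraries, with shared myosin reads a limit here too.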
